A study of Homo sapiens with 4 samples.

How the data were processed

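ChIP-seq signal was measured in 4 libraries from K562 cells, 2 with an antibody against DPF2 and 2 with an antibody against H3K14cr, with the group and replicate number of each taken from its title. Per the labels' protocols, formaldehyde-fixed cells were sonicated and immunoprecipitated, and the libraries were built with a commercial kit. The submitters' processing notes name Bowtie2, without a version, and the genome builds mm9 and hg19; duplicate treatment, mapping filters and the binning tool are not given in the sources used here. The coordinates run past the end of chromosome 1 of GRCh38 and were read as hg19. No control library was analysed here.

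The deposited signal files list 100 bp bins with at least 1 read, in each library on a grid of its own, with values scaled to a library of 10000000 reads and rounded to 2 decimals. Every value was divided by what 1 read was worth, which gave whole reads within a tolerance of 0.005 for all but 1, 3, 4 and 0 of the listed values in the DPF2 replicate 1, DPF2 replicate 2, H3K14cr replicate 1 and H3K14cr replicate 2 libraries (100%, 100%, 99.9999% and 100% whole). The recovered totals were 7787444, 13317496, 10880366 and 17369133 reads. No bin held more than 187 reads, below the 200 that a 100 bp bin can hold with 1 read per position and strand, and whether duplicates were removed is not known. Reads without molecular identifiers are not independent molecules, and all intervals cover counting error only.

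Reads were summed in 1 kb tiles on 24 chromosomes. A tile was called enriched in a library when a one-sided Poisson test against the larger of the chromosome mean and the mean of the surrounding 20 kb gave a Benjamini-Hochberg adjusted p of at most 0.001 with a fold of at least 3, and for an antibody when called in both of its libraries. Touching tiles were merged into regions. Signal files had been planned to be ranked by a fold without a p-value; since whole reads were recovered, the Poisson test was used, and the fold alone was an added alternative. Overlap was compared with 1000 circular shifts of a region set along each chromosome. Enriched tiles numbered 8058 and 12536 in the DPF2 libraries and 14553 and 16903 in the H3K14cr libraries.

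Tiles enriched for either antibody with a mean of at least 10 reads per library were tested with limma (trend) on log2(CPM + 0.5), at a Benjamini-Hochberg adjusted p of at most 0.05; fold changes on this scale understate the change of low tiles. edgeR's quasi-likelihood test on the recovered reads was an added alternative. Because the libraries of an antibody differed by no more than sampling noise over all 1 kb tiles together, these p-values measure technical spread. Named tiles are given with ratios of pooled reads and exact binomial intervals at 95% confidence. Over 1 kb tiles with 150 reads or more, the chi-square per degree of freedom was 2.27 for the DPF2 pair and 1.16 for the H3K14cr pair. Intervals at such tiles are therefore too narrow, more so for DPF2. In simulated data limma recovered 64% of 100 tiles changed 2-fold and 100% of 100 changed 4-fold among 12225, with 5 false calls.

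Tiles were named by rules set before the data were examined: the 10 with the largest log2 difference in each direction among called tiles whose libraries do not overlap between antibodies, and the 10 regions with the highest fold for each antibody, ranked by the lower library. Those rules and the test between antibodies were written for promoters and, as laid down beforehand, were applied to tiles because no annotation of hg19 was used here. Promoter shares, exon and intron shares and gene lists were not analysed here.

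Profiles were averaged over 3 kb on each side of the highest 100 bp bin of a tile in a library and measured in the other library of that antibody. Tiles among the top 0.1% of all 4 libraries and tiles on chromosome Y were left out. Widths were taken midway between the summit and flanks of 1 kb at each end, with 200 bootstrap draws over tiles. On simulated peaks of 600 and 1200 bp the measured widths were 594 and 1190 bp. Gene counts per chromosome came from the protein-coding entries of assembly GCF_000001405.40 (GRCh38.p14), with 100000 permutations for the correlations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16 were used.

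Alternatives covered tile size, fold and background, depth, the overlap that counts as shared, very high tiles, scaling, pseudocount, filter, test, the replicate number as a block and each library left out. Read-level alternatives for duplicates and mapping quality, and those that need promoters, were not run.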

Results

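The series mapped DPF2 and crotonylated lysine 14 of histone H3 (H3K14cr) by chromatin immunoprecipitation and sequencing (ChIP-seq) in K562, an established human leukaemia cell line with erythroid features. DPF2 is a subunit of BAF chromatin remodelling complexes whose paired PHD fingers bind acylated lysine 14 of histone H3. The labels describe 2 libraries for each antibody, all from wild-type cells. The libraries held 7787444 and 13317496 reads for DPF2, and 10880366 and 17369133 reads for H3K14cr. Positions are given on hg19, and regions are named by coordinates alone because no annotation of that build was used here.

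The libraries of the same antibody differed by less than the sampling noise over 1 kb tiles and were counted as 1 sample, so n = 1 for DPF2 and n = 1 for H3K14cr. The chi-square per degree of freedom between the DPF2 libraries was 0.982 over 1 kb tiles and 1.03 over 100 kb tiles, and between the H3K14cr libraries it was 0.985 and 0.999. Between antibodies it lay between 1.25 and 1.33 over 1 kb tiles and between 3.31 and 5.14 over 100 kb tiles. Over 1 Mb tiles it was 1.19 for DPF2 and 1.06 for H3K14cr, slightly above sampling noise, against 15.7 to 27.5 between antibodies. Another exception was a set of 312 tiles of 1 kb with 150 reads or more in the DPF2 pair, where the value was 2.27. Over 1169 such tiles in the H3K14cr pair it was 1.16. At the very high tile chr1:565001-566000 the DPF2 libraries had 163.6 and 113.0 CPM. How far a few such tiles give the value of 2.27 was not tested. Nothing in the labels says that the libraries of an antibody came from separate cultures. Differences between antibodies therefore have no replicate check, and every test compares these preparations through counting or technical spread only.

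The first comparison asked where each antibody was enriched. DPF2 was enriched in 5582 tiles of 1 kb, which formed 5100 regions, and H3K14cr in 10802 tiles, which formed 8628 regions. Most regions were a single tile: 90.7% for DPF2 and 75.8% for H3K14cr. The median enrichment over background was 4.55-fold for DPF2 and 4.41-fold for H3K14cr, and the enriched tiles held 1.84% and 3.60% of the reads. The widest region of both antibodies was chr5:134259001-134264000, at a mean of 4.57-fold for DPF2 and 4.39-fold for H3K14cr. It holds 3 of the tiles with the highest levels in all 4 libraries, at 30.5 to 70.8 CPM. The background of each tile included its neighbours, so the folds of this region understate its level. How far this background limits the width of regions was not tested. In simulated DPF2 libraries of the same depth, 20% of 200 tiles planted at 4-fold, 71% at 6-fold and 100% at 10-fold were recovered among 2591488 tiles, so weak sites were often missed at this depth. When the libraries of an antibody were summed before calling, DPF2 had 11881 regions and H3K14cr 13056; the background of the chromosome alone gave 18686 and 28998. A fold of at least 5 gave 1265 and 2361, and 500 bp tiles gave 2768 for DPF2. Without replicate 1, DPF2 had 10707 regions and H3K14cr 13067.

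Among the 10 regions with the highest enrichment for DPF2, 7 were also enriched for H3K14cr. Of these 7, 4 lay in tiles among the top 0.1% of all 4 libraries, and of the 6 regions outside such tiles 3 were shared. The highest was chr14:88237001-88238000, at 42.3-fold for DPF2 and 35.4-fold for H3K14cr, one of those very high tiles. By contrast, chr4:185655001-185656000 had 31.4-fold for DPF2 and 2.59-fold for H3K14cr, and chr12:53297001-53298000 had 24.6-fold and 2.30-fold. The remaining region not shared, chr8:87354001-87355000, was borderline. It had 25.5-fold for DPF2, and its H3K14cr folds were 2.99 in replicate 1 and 3.71 in replicate 2, against a threshold of 3. At chr16:78133001-78134000 both antibodies were enriched, at 29.7-fold for DPF2 and 4.56-fold for H3K14cr. All 10 of the highest H3K14cr regions were also enriched for DPF2, and 9 of them lay in tiles among the top 0.1% of all 4 libraries. The exception, chrX:108297001-108298000, had 20.6-fold for H3K14cr and 23.4-fold for DPF2.

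Regions of both antibodies were denser on gene-rich chromosomes. Chromosome 19 had the highest density, with 4.91 DPF2 regions and 8.87 H3K14cr regions per covered Mb, and chromosome X the lowest, with 0.640 and 1.67. Across 23 chromosomes without Y, the density of H3K14cr regions followed that of protein-coding genes counted in the GRCh38.p14 gene table (Pearson r = 0.954, permutation p = 1.0e-05, adjusted p = 2.0e-05; Spearman rho = 0.903, permutation p = 1.0e-05, adjusted p = 2.0e-05, where 1.0e-05 is the smallest that the permutations can give). For DPF2 the correlation was 0.842 by Pearson (permutation p = 6.0e-05, adjusted p = 6.0e-05) and 0.687 by Spearman (permutation p = 4.4e-04, adjusted p = 4.4e-04). Without chromosomes 19 and 17, r was 0.824 for H3K14cr and 0.530 for DPF2. Chromosome 22 departed from the pattern for DPF2, with 13.8 genes per covered Mb but 1.60 DPF2 regions, against 4.33 for H3K14cr. However, the windows of chr22:19000001-24000000 stood at 6.65 to 8.87 times the median read level. They raise the chromosome mean, below which the background of a tile was not set, so tiles elsewhere on chromosome 22 were harder to call. How far this gives the departure was not tested. Calls depend on read level, and whether copy number or a bias shared by the libraries sets these densities was not tested. The adjustment was over the 2 antibodies, and chromosomes of a cell line are not independent replicates.

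**Figure D1:**
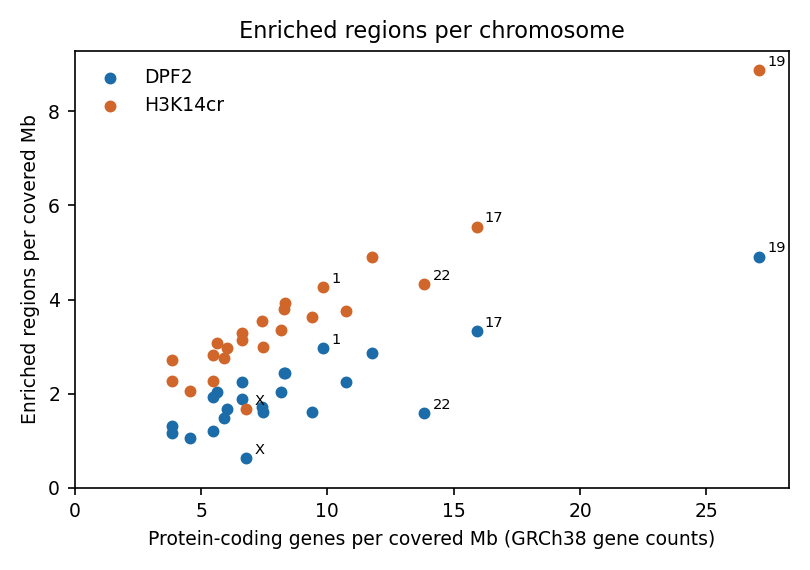
Enriched regions per covered Mb (y axis) against protein-coding genes per covered Mb (x axis) for 23 chromosomes, with each point a chromosome and an antibody. Chromosome 19 is highest for both antibodies, at 4.91 regions per Mb for DPF2 and 8.87 for H3K14cr.

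The second comparison asked how far DPF2 and H3K14cr occupied the same places. Of the 5100 DPF2 regions, 3835 (75.2%, 95% Wilson interval 74.0 to 76.4%) touched an H3K14cr region. Of the 8628 H3K14cr regions, 3834 (44.4%, 43.4 to 45.5%) touched a DPF2 region. After circular shifts along each chromosome the mean shares were 0.502% and 0.297%, and the highest of 1000 shifts gave 0.843% and 0.475% (one-sided permutation p = 0.000999 for both, the smallest that the shifts can give). The intervals cover counting error only. The H3K14cr share moved by more than 1.5 times with 500 bp tiles, to 18.8%, against 57.7% for DPF2.

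Sharing increased with the strength of enrichment. Among DPF2 tiles in the lowest of 5 equal groups by fold, 56.8% (53.8 to 59.6%) were also enriched for H3K14cr, against 85.3% (83.1 to 87.3%) in the highest group. The fourth DPF2 group was already at 84.8%. For H3K14cr tiles the share also enriched for DPF2 was 19.1% (17.5 to 20.8%) in the lowest group and 65.4% (63.4 to 67.4%) in the highest. The very high tiles were kept in these groups. Weak tiles were often missed in simulated DPF2 libraries (20% recovered at 4-fold, 100% at 10-fold). How far missed calls of the other antibody give this rise was not tested. Tiles called for 1 antibody alone were raised in the other: the median H3K14cr fold was 2.86 at the 1425 tiles called for DPF2 alone, and the median DPF2 fold was 2.99 at the 6645 tiles called for H3K14cr alone. Covered tiles called for neither had median folds of 0.674 for DPF2 and 0.623 for H3K14cr.

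**Figure D2:**
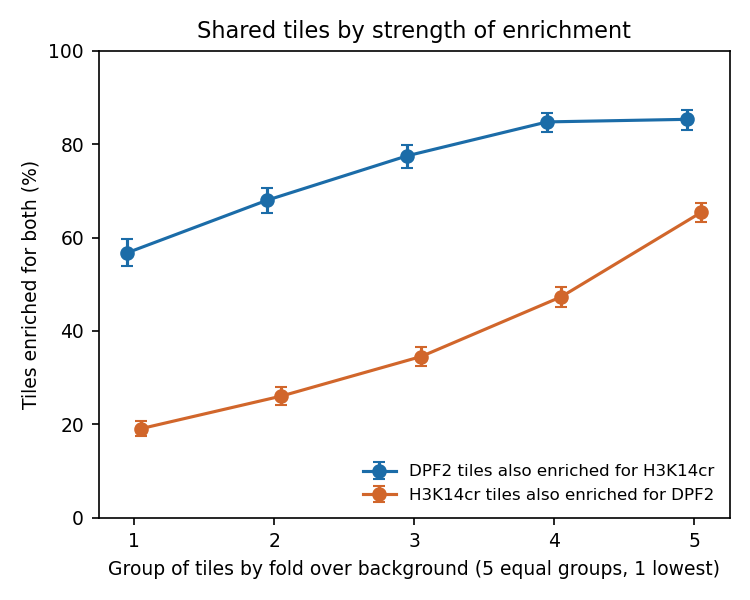
Percent of enriched 1 kb tiles that were also enriched for the other antibody (y axis), by 5 equal groups of tiles ranked by fold over background (x axis, 1 lowest); bars are 95% Wilson intervals. The share goes from 56.8% to 85.3% for DPF2 tiles and from 19.1% to 65.4% for H3K14cr tiles.

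Across the 12227 tiles enriched for either antibody the Spearman correlation of mean levels was 0.595 between DPF2 and H3K14cr, and 0.389 on folds over local background. Between single libraries it was 0.490 to 0.584 across antibodies, against 0.745 within DPF2 and 0.858 within H3K14cr. The tiles had been chosen by their calls in these libraries, and how far that choice sets the gap was not tested. Over all 2598309 covered 1 kb tiles the correlations were 0.682 within DPF2, 0.765 within H3K14cr and 0.658 to 0.751 between antibodies. After thinning to the shallowest library they were 0.603 within DPF2, 0.635 within H3K14cr and 0.598 to 0.604 between antibodies. These correlations are across tiles, which are not independent replicates.

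The third comparison asked which enriched tiles differed between the antibodies. A set of tiles had strong DPF2 signal and much lower H3K14cr signal. Over the 10 named tiles the fold over background was 5.26 to 31.4 for DPF2 and 0.790 to 2.59 for H3K14cr. The clearest was chr17:61920001-61921000, with 25.2 CPM for DPF2 and 1.96 for H3K14cr, a ratio of 12.4 in pooled reads (95% exact binomial interval 9.40 to 16.7). At chr8:144152001-144153000 the ratio was 19.4 (9.53 to 46.0), from 116 DPF2 reads and 8 H3K14cr reads. At chrX:129300001-129301000 it was 12.2 (7.27 to 21.9), and at chr4:185655001-185656000 it was 10.8 (7.64 to 15.8). At chr1:27018001-27019000 it was 7.72 (5.87 to 10.3), with folds over local background of 5.26 for DPF2 and 1.08 for H3K14cr. Over the 10 named tiles higher in DPF2 the ratio ran from 7.48 to 19.4.

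The tiles higher in H3K14cr differed less. At chr7:33101001-33102000 H3K14cr had 1.91 CPM and DPF2 0.252, a ratio of 6.85 (2.95 to 19.5). At chr6:34205001-34206000 the ratio was 3.89 (2.68 to 5.79), and at chr11:57193001-57194000 it was 3.34 (2.40 to 4.75). Over the 10 named tiles it ran from 3.16 to 6.85. The ratios of named tiles in both directions are of pooled reads scaled by library totals, and their intervals cover counting error only. The DPF2 libraries differed by more than sampling noise over tiles with 150 reads or more, so intervals there are too narrow. The tiles were chosen for large differences in the same reads, so their ratios may be overstated.

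**Figure D3:**
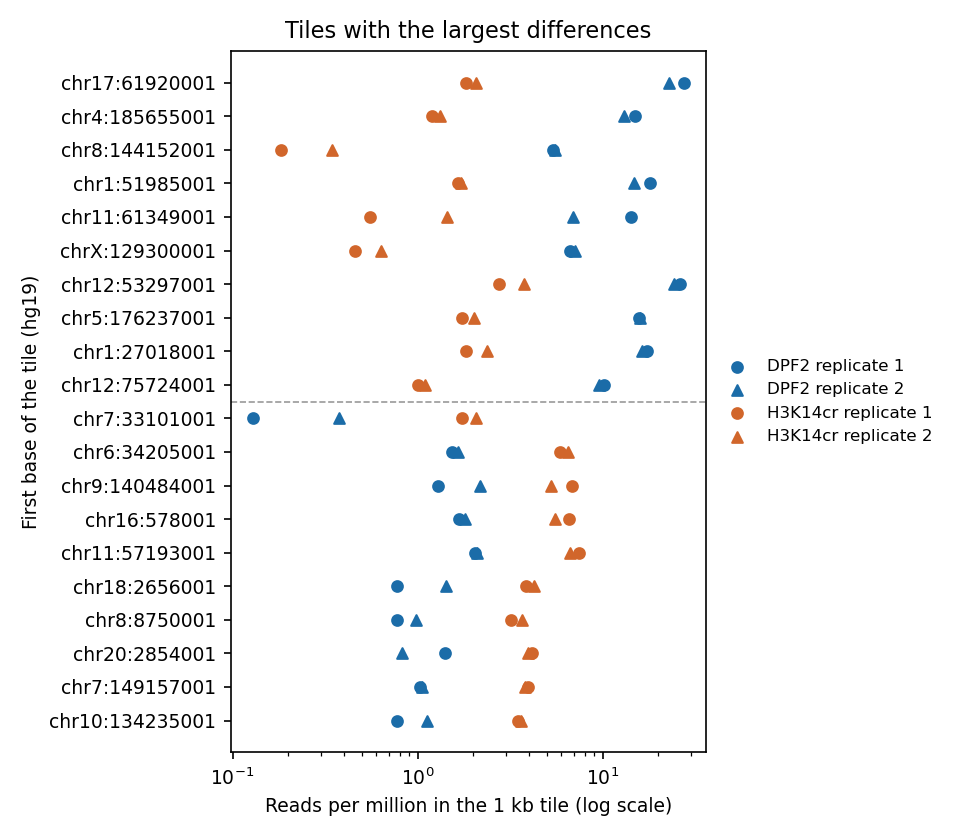
CPM in 1 kb tiles (x axis, log scale) for the 10 tiles with the largest difference in each direction (y axis, first base on hg19), with a point for each library. Tiles above the dashed line were higher in DPF2, by ratios of 7.48 to 19.4, and those below it were higher in H3K14cr, by 3.16 to 6.85.

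Across the 12225 enriched tiles tested, limma called 4350 at an adjusted p of at most 0.05: 512 higher in DPF2 and 3838 higher in H3K14cr. Of the tiles higher in DPF2, 384 were enriched for DPF2 alone and 127 for both. Of those higher in H3K14cr, 3185 were enriched for H3K14cr alone and 653 for both. The tiles had been chosen by calls in these same libraries, 6645 for H3K14cr alone and 1425 for DPF2 alone. Over all 255612 tiles with a mean of at least 10 reads, the counts were 516 and 3032. A difference of at least 4-fold on the log2(CPM + 0.5) scale was reached by 40 tiles higher in DPF2 and by 0 tiles higher in H3K14cr. With edgeR, whose scale is less compressed for low tiles, the counts were 64 and 1, and on folds over local background they were 52 and 2. Median-of-ratios factors gave 75 and 0, and a pseudocount of 2 CPM gave 10 and 0. The split depended on the scaling: with reads scaled by library totals the median log2 difference of DPF2 minus H3K14cr was -0.33, and 11.8% of the calls were higher in DPF2. With median-of-ratios factors the median was -0.02 and the counts were 1100 and 662 (62.4% higher in DPF2), and with quantile normalization they were 920 and 746 (55.2%). Without H3K14cr replicate 1 the calls were 1332, and without H3K14cr replicate 2 they were 1728. The numbers of tiles higher in each antibody thus describe levels relative to the scaling chosen.

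Tiles enriched for DPF2 alone were more often near H3K14cr tiles than random covered tiles were. Of the 384 such tiles called higher in DPF2, 103 (26.8%, 95% Wilson interval 22.6 to 31.5%) lay within 5 kb of an H3K14cr tile, and of the 1041 that were not, 343 did (32.9%, 30.2 to 35.9%). Among 20000 random covered tiles the share was 3.65% (3.40 to 3.92%). Touching tiles counted as near, so some pairs may be a single signal cut by the tile grid. The random tiles were not matched on read level. The first share was lower than the second by a two-sided Fisher's exact test (p = 0.0286), a comparison chosen after seeing the data, over tiles that are not independent and of which the first were selected for low H3K14cr. Tiles enriched for both antibodies were left out because their distance is 0 by choice.

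The signal also differed in width. With summits taken from replicate 1 and the profile measured in replicate 2, DPF2 at the 1399 tiles enriched for DPF2 alone had a width of 698 bp at the middle height between flank and summit (bootstrap SD 25.3 bp). H3K14cr at the 6579 tiles enriched for H3K14cr alone had a width of 1255 bp (SD 18.0 bp). At the 3961 tiles enriched for both, the widths were 1067 bp for DPF2 (SD 24.1 bp) and 1227 bp for H3K14cr (SD 28.8 bp). Around the summits of tiles enriched for DPF2 alone, H3K14cr formed a low mound of 1677 bp (SD 58.9 bp), 3.26 times its flanks, against 6.74 times for DPF2. Around the H3K14cr summits of tiles enriched for H3K14cr alone, DPF2 likewise formed a low mound of 1661 bp (SD 23.03 bp), 3.69 times its flanks. At tiles enriched for both, DPF2 was 1306 bp wide around H3K14cr summits (SD 29.7 bp), so a width depends on which antibody gives the summit. With summits from replicate 2 and the profile in replicate 1, the widths were 656 bp for DPF2 alone and 1191 bp for H3K14cr alone. The bootstrap SDs cover the choice of tiles only.

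**Figure D4:**
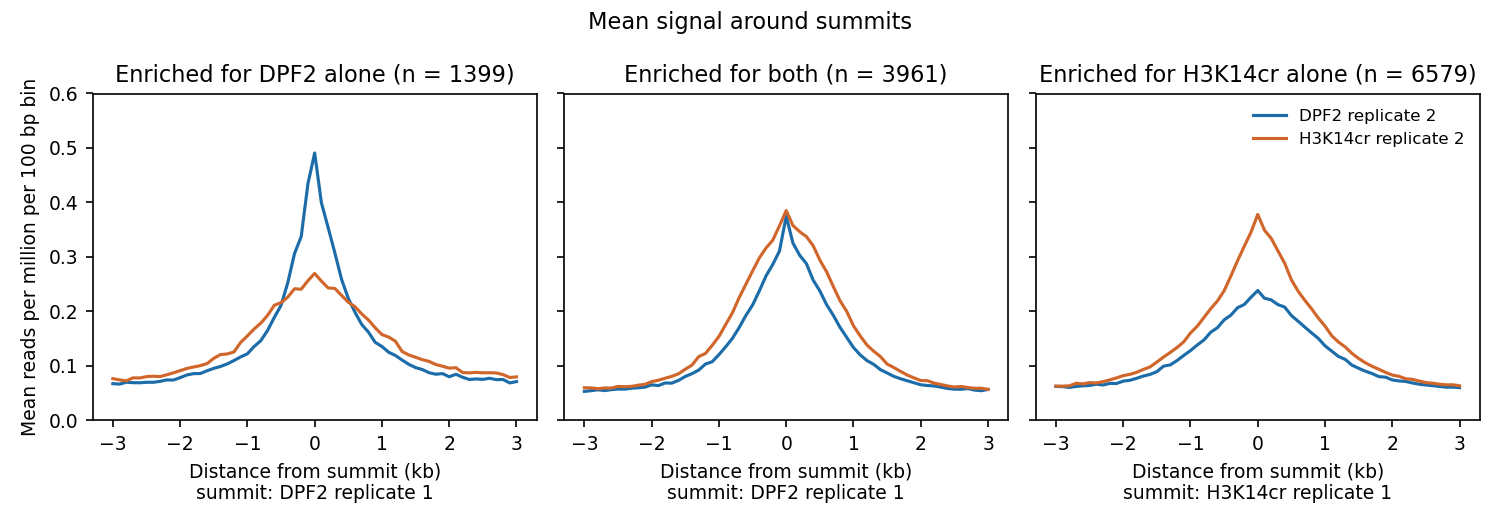
Mean CPM per 100 bp bin (y axis) within 3 kb of summits (x axis) in replicate 2 of each antibody, with summits taken from replicate 1 of DPF2 (left, middle) or H3K14cr (right). DPF2 has a width of 698 bp at tiles enriched for DPF2 alone and 1067 bp at tiles enriched for both, and H3K14cr has 1255 bp at tiles enriched for H3K14cr alone.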

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

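Chosen after seeing the data were the fold without a p-value, summed libraries, short shifts and thinned correlations. So were, for the correlation between antibodies, tiles with a mean of at least 5 reads and the very high tiles left out. For the test they were edgeR, fold over local background, the very high tiles left out, tiles with a mean of at least 10 reads, and 500 bp and 2 kb tiles. Both overlap shares stayed above all shifted shares in all 13 alternatives, from 57.7 to 83.2% for DPF2 regions and from 18.8 to 61.2% for H3K14cr regions, against at most 5.19% and 3.25% after shifts. The 20 named tiles kept their direction and their side of the threshold in 240 of 240 recomputed values (highest adjusted p = 0.00899, limma or edgeR); they were named for large differences, so little else was possible. Counts of regions moved with the calling rule. A fold of at least 5 gave 1265 regions for DPF2 and 2361 for H3K14cr, the chromosome background alone 18686 and 28998, and summed libraries 11881 and 13056. For DPF2, 500 bp tiles gave 2768 and a fold without a p-value 8400. With a single library per antibody, DPF2 had 7234 to 10707 regions and H3K14cr 11383 to 13067; 1 call is asked for instead of 2. Replicate correlations were 0.941 for DPF2 and 0.960 for H3K14cr over 10 kb tiles, 0.401 and 0.518 over tiles with a mean of at least 5 reads, and 0.603 and 0.635 after thinning to the shallowest library. The correlation of DPF2 with H3K14cr was 0.389 on folds over local background and 0.509 over tiles with a mean of at least 5 reads, and 0.490 to 0.584 with a replicate left out. Tiles that differed numbered 1762 with median-of-ratios factors (1100 higher in DPF2, 662 in H3K14cr), 1666 with quantile normalization (920 and 746) and 1645 on folds over local background (1235 higher in H3K14cr). With a library left out they numbered 1332 to 4700, with 281 to 701 higher in DPF2 and 1051 to 3999 higher in H3K14cr; the lone library was assumed to vary like the others. Tiles of 2 kb gave 304 higher in DPF2. The cause was not tested for these shifts in counts. edgeR called 4099. Deviations of same-numbered libraries correlated at -0.016, and the fit with a replicate block called 4230 tiles. That correlation cannot decide whether same-numbered libraries share more than a label. Libraries of an antibody differed by no more than sampling noise over 1 kb tiles, which leaves little to correlate. Duplicate, mapping-quality, promoter and gene-list alternatives were not run, since they need reads or an annotation not used here. Depth limits weak sites: in simulated DPF2 libraries 20% of tiles planted at 4-fold were recovered.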

Other observations

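Leaving out the very high tiles from the overlap was chosen before the data were examined, but the prediction for it was written after. The prediction for tiles matched on reads was written before its result was seen, and the other tests were chosen after. A few windows of 1 Mb stood out in all 4 libraries. Of 2770 windows, 6 had at least 6 times the median read level in every library: chr9:133000001-134000000 and the 5 windows from chr22:19000001 to 24000000, at 6.65 to 8.87 times. Without enriched tiles the levels were 6.49 to 8.56 times. No other window reached such levels in all libraries; the highest level of a library elsewhere was 5.39 times. In these windows 0.475% of tiles were enriched for DPF2 and 0.989% for H3K14cr, against 0.213% and 0.414% elsewhere. A tile of a given fold is called more readily where reads are more numerous, and whether the higher shares come from that was not tested.

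The agreement of libraries of the same antibody has more than 1 possible source. The higher chi-square per degree of freedom of the same-antibody pairs was 1.03 over 100 kb tiles, near what 1 preparation sequenced in 2 runs may give. Over 1 Mb tiles, however, the DPF2 pair reached 1.19. Over 1 kb tiles with 150 reads or more, it reached 2.27, against 1.16 for the H3K14cr pair. How far a few very high tiles give these values was not tested. Too few reads to see a difference as large as that between antibodies is argued against by their value of at least 3.31 at similar depth. Smaller differences, such as separate cultures may show, could still be missed. A single preparation therefore cannot be told apart from separate cultures that differ little, since the labels do not say how the libraries arose. No biological explanation was tested.

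The overlap of DPF2 and H3K14cr regions may have technical sources. Mitochondrial copies and collapsed repeats were checked by leaving out the very high tiles, which left 4915 DPF2 regions, 74.6% of them shared. Too few regions were dropped for the share to fall to the shifted level. The very high tiles are thus not the whole cause, but repeats below that cut stay open. Broad background and copy number are argued against, because shifts of 5 to 50 kb gave at most 1.33%. A bias of open chromatin or shearing common to all libraries cannot be told apart from shared occupancy: DPF2 had a median fold of 2.99 at tiles called for H3K14cr alone, and no control library was analysed here. Binding of DPF2 to crotonylated H3 stays open and untested.

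DPF2 signal at tiles enriched for DPF2 alone was narrower than H3K14cr signal at tiles enriched for H3K14cr alone. Choice of tiles on the same reads is argued against, since tiles and summits of replicate 1 gave a difference of -550 bp (SD 32.1 bp) in replicate 2. The width ratio of DPF2 over H3K14cr was 0.869 at tiles enriched for both and 0.556 at tiles enriched for either alone. Shorter DPF2 fragments as the whole cause are argued against, because DPF2 replicate 2 itself gave 1067 bp and 698 bp there. A contribution of fragment length stays open, since it need not change the width of every site by the same ratio. Summits placed better by more reads are argued against, since tiles enriched for DPF2 alone held fewer reads in the summit library (mean 27.3) than those enriched for H3K14cr alone (33.8); matched on reads, the difference was -462 bp (SD 48.5 bp). Binding of the antibody to another protein was not tested and stays open, and no biological explanation was tested.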
